A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

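The series holds 4 mRNA libraries, 2 of wild-type BY4741 and 2 of the tor1 deletion strain, assigned to strain and replicate by their titles. Per the labels' protocols, total RNA was purified with a column kit, poly(A) RNA was taken with oligo(dT) beads, and libraries were made with an Ion Torrent total RNA kit and amplified by emulsion PCR. The authors deposited raw read counts per gene for each library, as whole numbers. The submitters' processing notes name FastQC, Subread and featureCounts and the genome build sacCer3, without versions. Alignment settings, the annotation release and whether counting used strand are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart.

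The authors also deposited a table of log10 values for 6519 genes. Each value equalled log10 of the count divided by a constant per library, plus 1, with constants of 1.61, 1.03, 0.669 and 0.903 for wild-type libraries 1 and 2 and deletion libraries 1 and 2. The listed genes had a total of at least 10 counts, and the 608 features that were not listed had at most 9. This table entered as an alternative, as log2 of the back-calculated value plus 1, and the counts were used for the main results.

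Each count file held 7127 features and no row without a gene. Names, positions and sequences came from the R64 assembly annotation of S288C, to which 6047 identifiers were matched by systematic name and 122 by symbol. The 958 others, among them tRNA genes and reading frames without an entry in that annotation, kept the identifier of the files. The count files carry no coordinates, and all positions given are those of R64. A gene was taken to have a near-identical copy where a non-overlapping gene matched it at 90% identity or more over at least 50% of the shorter of the pair (blastn 2.17.0). This held for 256 tested genes, of which 118 were called, and their counts are uncertain because reads could be split between copies. Mitochondrial-genome genes had no count in any library.

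Depth ranged from 8060480 to 14446057 counts per library, where 3 counts, the upper limit that a count of 0 allows, correspond to 0.208 to 0.372 CPM. Intervals and floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. The 10 most abundant genes took 9.30% and 9.33% of counts in the wild type and 11.1% and 10.9% in the deletion. Replicates correlated at 0.992 (wild type) and 0.973 (deletion) across genes in log2 CPM, and libraries of different strains at 0.840 to 0.879, and genes are not independent replicates. The replicates differed by more than sampling noise (chi-square over degrees of freedom 19.1 and 70.6), so none was a duplicate deposit. The first principal component held 89.0% of the variance.

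Strains were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with group as the only term. Genes were filtered by filterByExpr, which left 6197 and removed 930, and scaled by TMM factors. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The biological coefficient of variation was 17.8%. SE is the absolute log2 fold change divided by the square root of F. CPM are TMM-normalised, with SD over the 2 libraries of a strain. Gene lists were fixed before the data were examined, 38 in all. They covered the TOR pathway, ribosome synthesis, nutrient regulons, stress, metabolism, lifespan, cell cycle and cell type, plus the auxotrophic markers and the neighbours of TOR1. The 35 with at least 3 tested members, apart from the marker list, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with TOR1 left out and p adjusted over the 35. Lists overlap, so their tests are not independent.

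The genes named were set by a rule fixed before the data were examined. It took TOR1, the auxotrophic markers and the neighbours of TOR1, then the 12 largest rises and 12 largest falls with adjusted p below 0.05, a mean log2 CPM of at least 4 and no overlap between strains, leaving out TOR1 and the markers. It further took the 4 members of each list with the smallest p, and up to 12 passing members of the TOR effector and lifespan lists. Other genes, mostly the few members of a list that went against the rest, were chosen after their values were seen. Single-gene values of 2 genes that would otherwise be named are not reported here.

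Alternatives fixed before the data were examined were DESeq2 1.42.0, the edgeR likelihood ratio test, limma-voom, RLE and upper quartile factors, library totals alone, no filter and a filter of 50 counts in 2 libraries, nuclear reading frames only, no ribosomal protein genes, a replicate block, other thresholds, the authors' table, and each library left out in turn. For the lists they were an estimated correlation and fry. With an estimated correlation camera works with only 2 residual degrees of freedom, so few lists could pass whatever their correlation. A GC content offset and thinning to equal depth were added after the data were seen. The script was tested on simulated counts of the same design, made from the means and library sizes of these samples. Over 6161 simulated genes of the tor1 deletion against wild type it recovered 62 of 100 genes changed 2-fold and 93 of 100 changed 4-fold, and called 5 unchanged genes. This simulation changed 200 genes, evenly up and down, with the same spread in both strains. How the script performs where 51.8% of genes are called, or where the deletion pair spreads more, was not simulated. A simulated change of the proteasome list was recovered, and no list that shares no gene with it was called among the 35 run. In this run genes varied independently, while the correlation estimated in the data was 0.603 for cytosolic ribosomal protein genes. False list calls among correlated genes were therefore not tested. Figures were drawn with matplotlib 3.10.9.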

Results

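Messenger RNA was profiled in Saccharomyces cerevisiae BY4741, a haploid MATa laboratory strain of the S288C background with mutations in HIS3, LEU2, MET15 and URA3, and in a derivative of it in which TOR1 was replaced by a kanamycin-resistance cassette. TOR1 encodes a Target of Rapamycin kinase, which acts in TOR complex 1 to couple nutrient supply to growth. Both strains were grown in minimal glucose medium with ammonium sulfate and the required supplements and were harvested in exponential growth. Each sample title also carries a time of 4 h. Poly(A)-selected RNA was sequenced on an Ion Torrent instrument, with 2 libraries per strain. The counts assigned to annotated features came to 14446057 and 9623963 in wild-type libraries 1 and 2, and to 8060480 and 10244377 in deletion libraries 1 and 2. Between 6541 and 6730 of the 7127 features had at least 1 read per library. The comparison asks how loss of TOR1 changes the transcriptome and the expression of genes tied to lifespan. The labels do not say that the libraries of a strain came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

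The count of the deleted gene followed the labels. TOR1 (YJR066W, chromosome X, positions 559416 to 566828 on the plus strand of the R64 assembly, a single coding exon) had 635 and 357 counts in the wild-type libraries and 0 and 1 in the deletion libraries. The pooled normalised ratio of wild type over deletion was 602, with an exact 95% counting interval of 108 to 23821 that covers counting error only. LEU2 had no count in any library, where 3 counts would correspond to 0.208 to 0.372 CPM, the count scaled to library size. MET17, the gene also called MET15, had 3, 3, 0 and 0 counts, and URA3 had 1, 0, 0 and 0. HIS3, mutated in this strain by the his3-1 allele, was measured at 1483 ± 207 CPM (SD, n = 2) in the wild type and 815 ± 371 CPM in the deletion, a difference that missed the threshold (edgeR quasi-likelihood adjusted p = 0.0648). Which part of HIS3 these reads cover was not determined. HIS3 was called lower with DESeq2 (adjusted p = 0.0126), the edgeR likelihood ratio test (adjusted p = 0.025), library totals, upper quartile factors, the replicate block and the GC offset, and without either deletion library. Of the neighbours of TOR1, ARP3, which encodes a subunit of the actin-nucleating Arp2/3 complex, rose by 1.29 ± 0.19 on the log2 scale, and YAE1 was at -0.52 ± 0.21, which did not pass but was called lower with library totals, with upper quartile factors and without either deletion library. Below, changes of single genes are log2 fold changes of deletion over wild type ± SE, with 2 libraries per strain.

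The 12 genes with the steepest increases in the tor1 deletion included 3 hexose transporter genes and a hexokinase gene. HXK1 (YFR053C, chromosome VI, 253592 to 255049), the hexokinase isoform repressed by glucose, rose 229-fold, from 48.2 ± 2.81 to 11033 ± 4717 CPM (SD, n = 2 per strain), with a log2 fold change of 7.84 ± 0.46. The high-affinity glucose transporter genes HXT6 (YDR343C, chromosome IV, 1159608 to 1161320) and HXT7 (YDR342C, chromosome IV, 1154216 to 1155928) rose by 6.61 ± 0.27 and 6.43 ± 0.43. Their sequences are nearly identical, so the division of reads between them is uncertain. HXT4, a further transporter gene, went from 10.9 ± 1.83 to 721 ± 253 CPM. TMA10 (YLR327C, chromosome XII, 783127 to 783387) reached the greatest abundance of this group, from 474 ± 12.8 to 25080 ± 1912 CPM. HSP26, a small heat shock protein gene, rose by 5.70 ± 0.33, DDR2, a multi-stress response gene, by 6.26 ± 0.31, and GSY1, a glycogen synthase gene, by 5.51 ± 0.25. The remaining members of the 12 steepest rises were RCK1, a protein kinase gene (6.16 ± 0.54), YNL194C, a plasma membrane protein gene (6.16 ± 0.23), DCS2 (5.55 ± 0.32) and YFR052C-A (6.17 ± 0.32). YFR052C-A has no entry in the annotation used here, so whether it shares reads with another gene was not checked. Its systematic name places it next to HXK1, so its rise may not be separate from that of HXK1. For these 12 genes the edgeR quasi-likelihood adjusted p lay between 6.29e-05 and 0.000268, and both deletion libraries lay above both wild-type libraries, which the selection required.

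**Figure D1:**
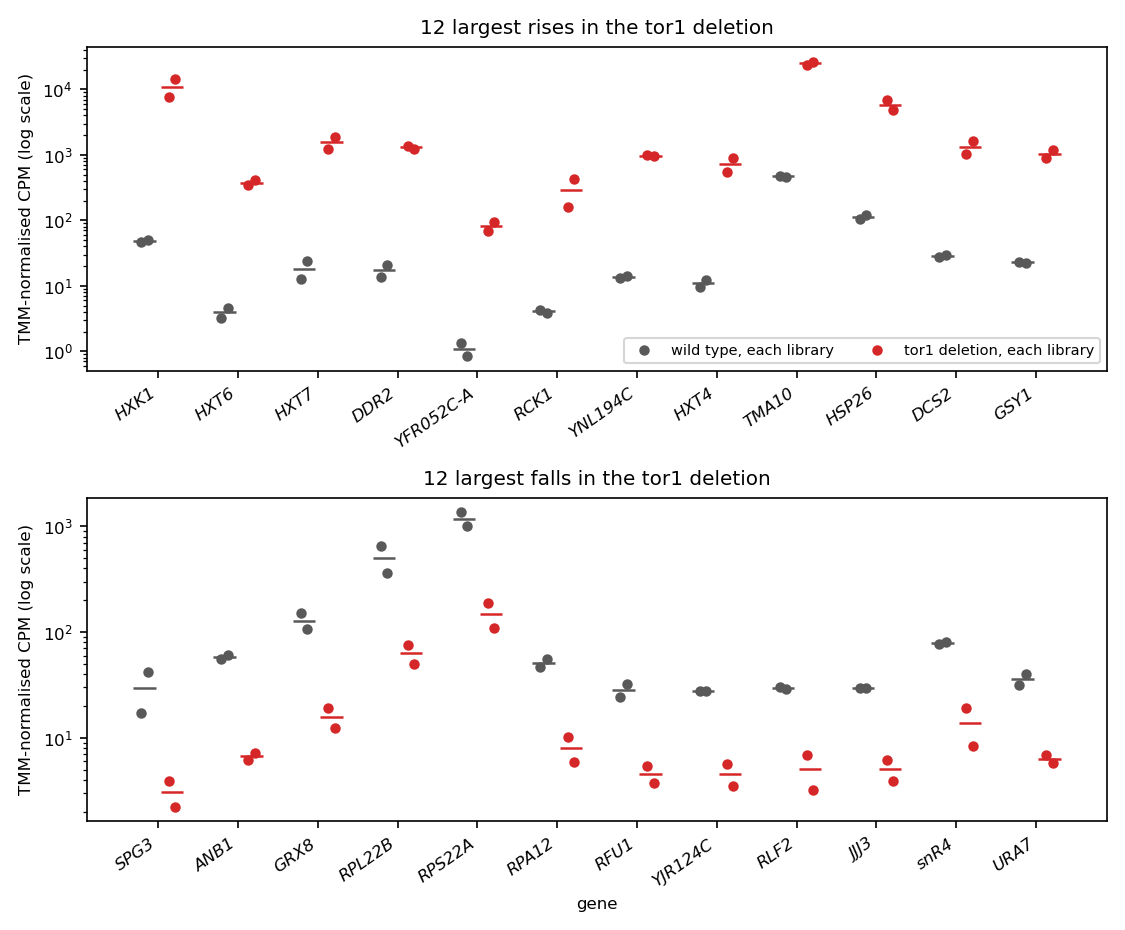
TMM-normalised CPM (log scale) of the 12 genes with the largest rise and the 12 with the largest fall, with a point for each library (2 wild type, 2 tor1 deletion) and a short line at the mean of each strain. HXK1 went from 48.2 to 11033 CPM and RPS22A from 1185 to 148 CPM. The libraries of the 2 strains do not overlap for any gene shown, because the selection required it.

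The 12 largest decreases among genes of at least moderate abundance were smaller than the rises. SPG3 (YDR504C, chromosome IV, 1456311 to 1456694) fell from 29.5 ± 17.4 to 3.05 ± 1.17 CPM. ANB1, the translation factor eIF5A isoform expressed under low oxygen, fell by 3.11 ± 0.22, although it is nearly identical in sequence to its paralog HYP2, which makes its counts uncertain. GRX8, a glutaredoxin gene, fell by 3.05 ± 0.29. A pair of cytosolic ribosomal protein genes was among them. RPL22B (YFL034C-A, chromosome VI, 64243 to 64932) fell from 503 ± 202 to 62.9 ± 17.7 CPM, and RPS22A (YJL190C, chromosome X, 74910 to 75302), which has a near-identical copy, fell from 1185 ± 244 to 148 ± 55.7 CPM. RPA12, an RNA polymerase I subunit gene, fell by 2.69 ± 0.30, URA7, a CTP synthase gene, fell by 2.51 ± 0.26, RLF2, a chromatin assembly factor subunit gene, fell by 2.58 ± 0.36, and snR4, a small nucleolar RNA gene, fell by 2.55 ± 0.36. Small nucleolar and nuclear RNA genes together took 0.294% and 0.265% of wild-type counts and 0.143% and 0.104% of deletion counts. RFU1 (-2.64 ± 0.30), YJR124C (-2.61 ± 0.29) and JJJ3 (-2.57 ± 0.29) completed the group. The edgeR quasi-likelihood adjusted p of these 12 genes lay between 0.000127 and 0.00229.

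Over all tested genes the 2 strains differed widely. Of 6197 genes tested, 1665 were higher and 1543 lower in the deletion (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), so that 51.8% were called. Calls in both directions within a list, described below, therefore do not by themselves set that list apart. A fold change of at least 2 was reached by 1061 of the higher and 997 of the lower genes, of at least 4 by 340 and 197, and of at least 16 by 64 and 8. The libraries of the strains did not overlap for 78.9% of genes, where chance gives 33.3%. The split between higher and lower calls rested on the normalisation. Higher genes made up 51.9% of the calls with TMM factors, 33.6% with library totals alone (1179 higher, 2328 lower) and 30.7% with upper quartile factors (1110 higher, 2508 lower), which moved the median log2 fold change of all genes by -0.33 and -0.39. Without wild-type library 1 the calls numbered 1045 higher and 915 lower, and without wild-type library 2 they numbered 1073 and 939.

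Of 138 genes on the cytosolic ribosomal protein list, 136 fell, with equal counts when p was adjusted over the list alone, and the median log2 fold change was -1.73. The exceptions were RPL41A and RPL15B, at -0.40 ± 0.28 and -0.36 ± 0.29. This list was drawn by gene name alone, by a rule that also takes RPP1, an RNase P subunit gene. RPS28B fell by 2.39 ± 0.20, RPS0B fell by 2.22 ± 0.19, RPS1B fell by 2.21 ± 0.21 and RPL6B fell by 2.16 ± 0.18. Many genes of this family, among them RPS28B, RPS1B and RPL6B, have near-identical copies that could exchange reads. The family stood below the other genes (camera adjusted p = 2.87e-33, and adjusted p = 0.363 with an estimated correlation). Among 117 ribosome biogenesis genes, 102 fell and 1 rose, against 1 up and 107 down with p adjusted over the list alone, with a median of -1.36 (camera adjusted p = 1.63e-19, and adjusted p = 0.145 with an estimated correlation). BFR2 fell by 2.32 ± 0.22, NOG2 fell by 2.06 ± 0.19, MRT4 fell by 1.93 ± 0.20 and CBF5, the pseudouridine synthase of box H/ACA particles, fell by 1.73 ± 0.17. RIO1, a kinase gene named after its value was seen, rose by 0.70 ± 0.22. The call of RIO1 ended without either wild-type library and with library totals or upper quartile factors, and 3 genes of this list rose without deletion library 1. NOG2 overlaps an intronic snoRNA gene, and whether counting used strand is not given in the sources used here. In the RNA polymerase I and III list 18 of 35 genes fell and the other 17 did not pass, against 0 up and 19 down with p adjusted over the list alone (camera adjusted p = 6.02e-05, and adjusted p = 0.232 with an estimated correlation). With library totals 25 of these polymerase genes fell, and with upper quartile factors 28. The polymerase I subunit genes RPA49, RPA135, RPA34 and RPA12 fell, with changes of -2.22 ± 0.20, -2.17 ± 0.18, -1.59 ± 0.18 and -2.69 ± 0.30. Of 37 translation initiation and elongation factor genes, 11 fell and 4 rose, with equal counts when p was adjusted over the list alone (camera adjusted p = 0.0458, and adjusted p = 0.619 with an estimated correlation). RPG1 and GCN3, subunits of eIF3 and eIF2B, fell, with changes of -1.80 ± 0.17 and -1.45 ± 0.18, as ANB1 did. HEF3, an elongation factor 3 paralog, rose by 1.92 ± 0.23. The other genes that rose were CAM1, SUI1 and PAB1, named after their values were seen. The call of this list ended without wild-type library 2 (camera adjusted p = 0.177), without deletion library 1 (0.125), with the replicate block (0.0677), with no low-count filter (0.0525) and with fry, a rotation test (0.0872). Without wild-type libraries 1 and 2, 7 and 5 translation factor genes fell, and without deletion library 2, 18 did, while 20 fell with library totals and 22 with upper quartile factors. Leaving out either wild-type library left 2 rises among them.

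In the list of targets of the general stress transcription factors Msn2 and Msn4, 64 of 70 genes rose and the other 6 did not pass, against 65 up and 0 down with p adjusted over the list alone, and the median log2 fold change was 3.64, a 12.5-fold rise (camera adjusted p = 8.16e-56, and adjusted p = 0.145 with an estimated correlation). CTT1, cytosolic catalase, went from 36.8 ± 2.57 to 974 ± 37.2 CPM, SOL4 rose by 5.15 ± 0.22, FMP16 by 4.55 ± 0.19 and YGP1 by 5.39 ± 0.25. Among 39 oxidative stress defence genes 24 rose, 4 fell and 11 did not pass, with equal counts when p was adjusted over the list alone (camera adjusted p = 5.45e-06, and adjusted p = 0.232 with an estimated correlation). Besides CTT1, these included SOD2, mitochondrial superoxide dismutase (2.48 ± 0.18), PRX1, mitochondrial peroxiredoxin (2.54 ± 0.20), and GPX1 (2.91 ± 0.19). The 4 that fell, named after their values were seen, were ATR1, GPX2, GRX3 and GRX4. The proteasome list rose in 32 of 34 members, with equal counts when p was adjusted over the list alone, and a median of 1.05 (camera adjusted p = 1.46e-06, and adjusted p = 0.232 with an estimated correlation). PRE4, RPN12, PRE7 and RPN10 rose by 1.56 ± 0.18, 1.30 ± 0.17, 1.38 ± 0.19 and 1.90 ± 0.26, and RPN4, the transcription factor of proteasome genes, did not pass, at 0.38 ± 0.22. Of 36 autophagy genes, 22 rose and 2, ATG2 and ATG10, fell, against 24 up and 2 down with p adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.232 with an estimated correlation). ATG8, the ubiquitin-like protein of the autophagosome membrane, rose by 2.18 ± 0.17, ATG39 by 2.48 ± 0.19, ATG34 by 2.58 ± 0.22 and ATG42 by 2.24 ± 0.22. Chaperone genes of the Hsf1 regulon did not pass as a list. Of 32, 13 rose, 3 (CUR1, HCH1 and SSA2) fell and 16 did not pass, against 13 up and 4 down with p adjusted over the list alone, and the median was 0.32 with TMM, -0.02 with library totals and -0.07 with upper quartile factors (camera adjusted p = 0.2, and adjusted p = 0.715 with an estimated correlation). SSE2, HSP42, SSA1 and HSP104 rose by 2.26 ± 0.17, 1.90 ± 0.25, 1.72 ± 0.22 and 1.51 ± 0.20, where SSA1 has a near-identical copy in SSA2. Without wild-type libraries 1 and 2, 19 and 20 proteasome genes and 5 and 7 chaperone genes rose, and without deletion library 2, 20 chaperone genes did. Without deletion library 1, 7 chaperone genes fell. Leaving out either wild-type library left 2 falls among oxidative stress genes, and leaving out wild-type library 1 left 1 fall among autophagy genes. With library totals and upper quartile factors 9 and 7 chaperone genes rose and 6 and 7 fell.

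**Figure D2:**
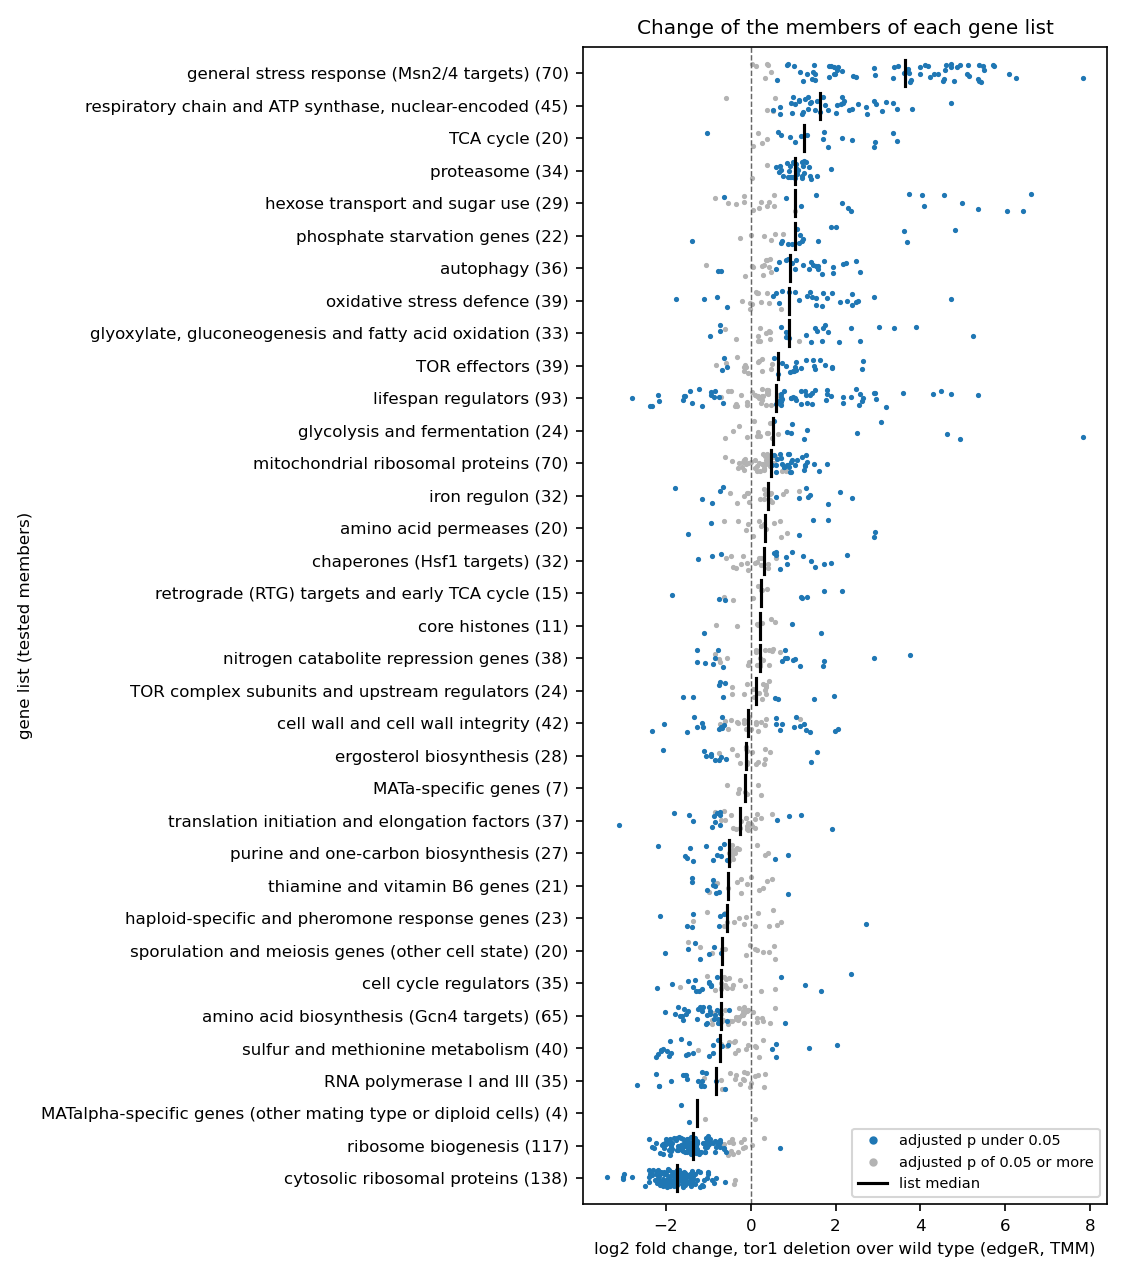
Log2 fold change of tor1 deletion over wild type (x axis, TMM normalisation) for each tested member of the 35 gene lists (y axis, number of tested members in brackets), with blue points for genes past the edgeR threshold, grey points for the others and a black line at the median of each list. General stress genes lie at the top with a median of 3.64 and cytosolic ribosomal protein genes at the bottom with a median of -1.73. With library totals the medians of the TOR complex, nitrogen catabolite repression, retrograde, chaperone and core histone lists turn negative, and with upper quartile factors that of the amino acid permeases does too.

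In the hexose transport and sugar use list 15 of 29 genes rose, 13 did not pass and 1, the glucose sensor gene RGT2, fell, with equal counts when p was adjusted over the list alone (camera adjusted p = 3.96e-08, and adjusted p = 0.363 with an estimated correlation). In addition to HXT4 and HXT6, MTH1 and MIG1, a negative regulator of glucose-induced transporter genes and a glucose repressor, rose by 4.10 ± 0.20 and 3.74 ± 0.20. No sugar measurement accompanies the libraries. Of 24 glycolysis and fermentation genes 11 rose and the other 13 did not pass, against 10 up and 0 down with p adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.363 with an estimated correlation). The leading members were HXK1 and the minor isoform genes GLK1, TDH1 and PYK2, encoding glucokinase, a glyceraldehyde-3-phosphate dehydrogenase and a pyruvate kinase, which rose by 4.93 ± 0.28, 4.63 ± 0.26 and 3.07 ± 0.19. TDH1 has a near-identical copy, and GLK1 overlaps another annotated gene. Nuclear-encoded respiratory chain and ATP synthase genes rose in 41 of 45 cases, against 43 up and 1 down with p adjusted over the list alone, with a median of 1.64 (camera adjusted p = 2.91e-18, and adjusted p = 0.232 with an estimated correlation). CYC7, the minor cytochrome c isoform, rose by 4.72 ± 0.23, STF1 by 3.81 ± 0.22, SDH1 by 3.45 ± 0.21 and HAP4, the activating subunit of the transcription complex for respiratory genes, by 2.94 ± 0.18. Of 20 TCA cycle genes 15 rose and 1, MAE1, fell, with equal counts when p was adjusted over the list alone (camera adjusted p = 1.19e-06, and adjusted p = 0.363 with an estimated correlation). SDH1, MDH1, SDH2 and LSC2 were foremost, the latter 3 at 2.93 ± 0.18, 2.91 ± 0.21 and 2.38 ± 0.18. Among 33 genes of the glyoxylate cycle, gluconeogenesis and fatty acid oxidation 19 rose and 3 fell, against 20 up and 3 down with p adjusted over the list alone (camera adjusted p = 0.000104, and adjusted p = 0.41 with an estimated correlation). ALD4, mitochondrial aldehyde dehydrogenase, rose by 5.23 ± 0.29, ADR1 and CAT8, transcription activators of these pathways, by 3.38 ± 0.20 and 2.08 ± 0.20, and MDH2 by 3.03 ± 0.24. The 3 that fell were SIP4, FBP1, encoding the gluconeogenic fructose-1,6-bisphosphatase, and ADH2, encoding the ethanol-consuming alcohol dehydrogenase, and these were named after their values were seen. Mitochondrial ribosomal protein genes rose in 30 of 70 cases and the other 40 did not pass, against 29 up and 0 down with p adjusted over the list alone (camera adjusted p = 0.00599, and adjusted p = 0.242 with an estimated correlation), with MRP8, MRP51, MRP20 and MRPL1 at 1.80 ± 0.20, 1.61 ± 0.18, 1.48 ± 0.17 and 1.33 ± 0.18. The mitochondrial ribosomal protein list was drawn by gene name alone, MRP8 included, and what its members encode was not checked. The 31 genes of the mitochondrial genome had no count in any library and could not be compared. Without wild-type libraries 1 and 2, 6 and 7 glycolysis genes and 13 and 14 mitochondrial ribosomal protein genes rose, and without deletion library 2, 46 of the latter did. With library totals and upper quartile factors 16 and 14 mitochondrial ribosomal protein genes rose and 2 and 5 fell, and 8 glycolysis genes rose and 3 fell with each. In the hexose list 3 and 4 genes fell with these scalings. Leaving out either wild-type library left 1 fall in the glyoxylate list and ended the call of RGT2. Without deletion library 1, 6 mitochondrial ribosomal protein genes fell.

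Genes for the TOR complexes and their regulators went both ways, as did the tested genes as a whole, and more TOR effector genes rose than fell. Of 24 genes for TOR complex subunits and upstream regulators, 4 rose and 6 fell, with equal counts when p was adjusted over the list alone. SLM1, a TOR complex 2 substrate gene that overlaps another annotated gene, rose by 1.97 ± 0.18 and FPR1, the rapamycin-binding immunophilin, by 1.48 ± 0.23. TSC11, a TOR complex 2 subunit, fell by 1.60 ± 0.23 and RTC1, a SEACAT subunit, fell by 1.36 ± 0.19. TOR2, the paralogous kinase gene named after its value was seen, was at 0.26 ± 0.23 and did not pass. The list's median was 0.13 and its mean 0.02, and fry placed it higher, while camera placed it lower (camera adjusted p = 0.811, and adjusted p = 0.826 with an estimated correlation). With library totals and upper quartile factors the median was -0.20 and -0.27. Of 39 TOR effector genes 21 rose and 3 (GLN3, TOD6 and IFH1) fell, against 22 up and 3 down with p adjusted over the list alone (camera adjusted p = 0.00599, and adjusted p = 0.43 with an estimated correlation). The 12 of these with the smallest p were GIS1 (2.65 ± 0.21), MSN4 (2.63 ± 0.27), YPK2 (1.93 ± 0.17), YAK1 (1.92 ± 0.17), CDC55 (1.76 ± 0.23), STB3 (1.63 ± 0.21), MAF1 (1.49 ± 0.16), DOT6 (1.47 ± 0.16), SCH9 (1.30 ± 0.25), TPD3 (1.08 ± 0.21), SIT4 (1.08 ± 0.16) and RRD2 (1.05 ± 0.19), and all 12 rose. They include the S6 kinase homolog SCH9, the RNA polymerase III repressor MAF1, the ribosome biogenesis repressors DOT6 and STB3, and subunits and regulators of phosphatase 2A and its relatives. YAK1 overlaps another annotated gene, and its counts are uncertain. Without wild-type library 2 the call of RRD2 ended (0.94, edgeR adjusted p = 0.0513). Leaving out either wild-type library left 2 rises and 2 falls in the TOR complex list and ended the 3 calls of lower effector genes. Without deletion libraries 1 and 2, 9 and 7 genes of the TOR complex list rose and 5 and 7 effector genes fell. With library totals and upper quartile factors, 17 and 14 effector genes rose and 6 and 8 fell, and in the TOR complex list 2 rose and 8 and 9 fell.

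Nitrogen use and permease genes went both ways, as did the tested genes as a whole, and genes of amino acid, sulfur and purine synthesis were more often lower than higher. Among 38 nitrogen catabolite repression genes 11 rose and 7 fell, with equal counts when p was adjusted over the list alone, and the median was 0.22 with TMM, -0.12 with library totals and -0.17 with upper quartile factors (camera adjusted p = 0.553, and adjusted p = 0.653 with an estimated correlation). The proline use genes PUT1 and PUT4 rose by 3.75 ± 0.23 and 2.91 ± 0.53 and UGA1, a GABA transaminase gene, by 1.70 ± 0.18. ARO9, an aromatic aminotransferase gene, fell by 0.89 ± 0.17, a call that ended without wild-type library 1 (-0.85, edgeR adjusted p = 0.0647). Of 15 retrograde targets 5 rose (CIT1, CIT2, CIT3, PDH1 and PYC1) and 3 fell, IDP1 and LYS21 among them, with equal counts when p was adjusted over the list alone, and the median was 0.24 with TMM, -0.09 with library totals and -0.15 with upper quartile factors (camera adjusted p = 0.372, and adjusted p = 0.707 with an estimated correlation). CIT1 rose by 2.14 ± 0.19, PDH1 by 1.73 ± 0.20, CIT3 by 1.34 ± 0.21 and PYC1 by 1.19 ± 0.19. Of 20 amino acid permease genes 5 rose and 2 (TAT1 and PTR2) fell, with equal counts when p was adjusted over the list alone and a median of 0.33 that was -0.06 with upper quartile factors (camera adjusted p = 0.352, and adjusted p = 0.653 with an estimated correlation). AGP2, DIP5 and AGP1 rose by 2.93 ± 0.24, 1.83 ± 0.29 and 1.46 ± 0.21, and TAT1, which overlaps a non-coding RNA gene, fell by 1.47 ± 0.17. Amino acid biosynthesis genes fell in 31 of 65 cases and 1, TRP1, rose, with equal counts when p was adjusted over the list alone (camera adjusted p = 7e-05, and adjusted p = 0.629 with an estimated correlation). ARG8, ARO7, HOM3 and TYR1 fell, with changes of -2.02 ± 0.28, -1.79 ± 0.18, -1.66 ± 0.20 and -1.49 ± 0.22. Of 40 sulfur and methionine genes 21 fell and 5 rose, against 5 up and 22 down with p adjusted over the list alone (camera adjusted p = 0.00102, and adjusted p = 0.43 with an estimated correlation). SEO1, MET22 and MET5 fell, with changes of -2.24 ± 0.29, -2.11 ± 0.20 and -1.94 ± 0.20, and the cysteine transporter gene YCT1 rose by 2.03 ± 0.19. The other 4 that rose were AGP3, MET12, MET30 and GSH1. Purine and one-carbon genes fell in 12 of 27 cases and 2, ADE16 and SHM1, rose, against 2 up and 13 down with p adjusted over the list alone (camera adjusted p = 0.00561, and adjusted p = 0.363 with an estimated correlation). IMD2, APT1, ADE4 and GCV2 fell, with changes of -1.55 ± 0.18, -1.50 ± 0.18, -1.44 ± 0.18 and -1.36 ± 0.18. Members of these lists outside the 4 with the smallest p were named after their values were seen. With either library totals or upper quartile factors 5 nitrogen catabolite repression genes rose and 10 fell, so that the balance of calls turned. Those scalings gave 50 and 48 amino acid biosynthesis genes and 22 purine genes each that fell. Without wild-type libraries 1 and 2, 5 and 6 nitrogen catabolite repression genes rose and 2 and 4 fell, 20 and 18 amino acid biosynthesis genes fell and 7 and 6 purine genes fell. Leaving out either of them also left 1 fall among retrograde targets, 2 rises among sulfur genes and 1 fall among permeases, and ended the 2 rises among purine genes. Without deletion library 1, 47 amino acid biosynthesis and 19 purine genes fell and 11 permease genes rose. Without deletion libraries 1 and 2, 15 and 16 nitrogen catabolite repression genes rose and 11 and 10 fell. Amino acid biosynthesis genes that rose numbered 3 and 5 in these settings, and purine genes that rose 5 and 3. The call of TRP1 ended without either wild-type library and with upper quartile factors. With each of the scalings 2 sulfur genes rose, 4 permease genes fell and the 2 rises among purine genes ended. Without either deletion library 4 permease genes fell.

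Lifespan regulators, the group the study set out to examine, contained both rises and falls. Of 93 genes on a list fixed before the data were examined, 44 rose, 18 fell and 31 did not pass, with equal counts when p was adjusted over the list alone, and the median was 0.59 (camera adjusted p = 0.000261, and adjusted p = 0.301 with an estimated correlation). The list of lifespan genes used by the submitters was not used here. With library totals 33 rose and 24 fell, with a median of 0.26, and with upper quartile factors 32 rose and 25 fell, with a median of 0.19. Genes for the protein kinase A pathway, which opposes the stress response, were among those that rose, with TPK2 at 3.60 ± 0.20 and BCY1, the inhibitory subunit, at 2.92 ± 0.19. Stress protection genes included HSP12 (5.35 ± 0.31), CTT1 and SOD2. Mitochondrial and acetate metabolism was represented by ALD6 (4.49 ± 0.29), ACH1 (4.30 ± 0.24), NDI1, the internal NADH dehydrogenase (3.19 ± 0.22), and HAP4, and autophagy by ATG8. ELO3, a fatty acid elongase gene listed under its older name SUR4, was the only one of the 12 members with the smallest p that fell (-2.37 ± 0.18). Among the 57 members in no other list 27 rose and 12 fell, and among the 36 also in another list 17 rose and 6 fell. SIR2, the silencing deacetylase gene, rose by 0.74 ± 0.22 and PNC1, the nicotinamidase gene, by 2.92 ± 0.24. FOB1, the replication fork block gene, fell by 0.65 ± 0.20, and these 3 were named after their values were seen.

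The remaining lists covered phosphate, metals, vitamins, sterols, the cell wall, chromatin, division and cell type. Phosphate starvation genes rose in 15 of 22 cases and 1, PHO3, fell, with equal counts when p was adjusted over the list alone (camera adjusted p = 0.000206, and adjusted p = 0.232 with an estimated correlation). The phosphate transporter genes PHO89 and PHO84 rose by 4.81 ± 0.34 and 3.62 ± 0.25, SPL2 by 3.68 ± 0.39 and PHO81 by 1.89 ± 0.18. PHO84 overlaps a non-coding RNA gene, so its counts are uncertain. Cell cycle regulators fell in 13 of 35 cases and rose in 4, against 4 up and 15 down with p adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.301 with an estimated correlation). The cyclin gene PCL1 and the replicative helicase gene MCM6 fell, with changes of -2.20 ± 0.28 and -1.32 ± 0.21. WHI5 and SIC1, inhibitors of entry into S phase, rose by 1.66 ± 0.26 and 1.28 ± 0.18, as did CLN3 and CLB3, named after their values were seen. Iron regulon genes rose in 8 of 32 cases and fell in 5, against 7 up and 5 down with p adjusted over the list alone (camera adjusted p = 0.483, and adjusted p = 0.749 with an estimated correlation), with MRS4, FTH1 and CCC2 up by 1.82 ± 0.16, 1.39 ± 0.19 and 1.35 ± 0.22 and the biotin transporter gene VHT1 down, at -1.78 ± 0.27. The other 4 that fell were ISU2, FRE2, ARN2 and ATX1. Of 21 thiamine and vitamin B6 genes 8 fell and 1, THI7, rose, with equal counts when p was adjusted over the list alone (camera adjusted p = 0.0963, and adjusted p = 0.363 with an estimated correlation). PET18, PHO3, SNO1 and THI3 fell, with changes of -1.39 ± 0.29, -1.38 ± 0.24, -1.04 ± 0.19 and -0.74 ± 0.16, the last of these without a call when either wild-type library was left out (-0.72 and -0.74). With the GC offset, added after the data were seen, the thiamine list passed camera (adjusted p = 0.0181). Of 28 ergosterol genes 9 fell and 2 rose, with equal counts when p was adjusted over the list alone (camera adjusted p = 0.232, and adjusted p = 0.43 with an estimated correlation). ERG28 and ERG9 rose by 1.56 ± 0.19 and 1.42 ± 0.19, and CYB5 and UPC2 fell, with changes of -2.08 ± 0.30 and -1.09 ± 0.22, with UPC2 not passing without wild-type library 1 (-1.03). Cell wall genes rose in 12 of 42 cases and fell in 12, against 12 up and 13 down with p adjusted over the list alone (camera adjusted p = 0.684, and adjusted p = 0.743 with an estimated correlation). The median of this list was -0.07 and its mean -0.03, and camera placed it lower and fry higher. With library totals 8 cell wall genes rose and 16 fell, with a median of -0.40, and with upper quartile factors 8 rose and 19 fell, with a median of -0.46. The same scalings gave 24 and 26 cell cycle genes, 13 and 17 ergosterol genes, 11 and 12 thiamine genes and 6 and 8 iron genes that fell, beside 6 iron genes that rose with each. YPS1 and PIR3 rose by 2.07 ± 0.18 and 1.99 ± 0.28, and UTR2 and CHS3 fell, with changes of -2.34 ± 0.19 and -1.34 ± 0.19. Without wild-type library 1, 8 cell cycle genes fell and 7 cell wall genes rose, and without deletion libraries 1 and 2, 21 and 22 cell cycle genes fell and 18 and 13 iron genes rose. Without wild-type libraries 1 and 2, 3 thiamine genes each and 2 and 5 ergosterol genes fell, beside 3 iron genes and 1. Leaving out either of them left 6 falls among cell wall genes. Without deletion library 1, 7 ergosterol genes rose. The call of THI7 ended with either of the other scalings and without wild-type library 1.

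Among 11 core histone genes HTB1 and HTA1 rose by 1.65 ± 0.21 and 0.97 ± 0.25 and HTB2 fell by 1.09 ± 0.26, with equal counts when p was adjusted over the list alone, a median of 0.23 that was -0.11 with library totals and -0.17 with upper quartile factors, and no list-wide shift (camera adjusted p = 0.655, and adjusted p = 0.826 with an estimated correlation). HTA1 has a near-identical copy. Its call ended without either wild-type library (0.95 and 1.00) and with upper quartile factors (0.57), and that of HTB2 ended without wild-type library 2 (-0.93). HHT1, which also has a near-identical copy, was at 0.57 ± 0.21 and did not pass, but was called higher with DESeq2, the likelihood ratio test, limma-voom and the authors' table and without either deletion library. Genes specific to MATa cells were well expressed in both strains, with STE2, the alpha-factor receptor gene, at 1433 ± 95.6 CPM in the wild type and 1166 ± 407 CPM in the deletion. None of 7 MATa-specific genes passed the edgeR quasi-likelihood test, 0 had an unadjusted p below 0.05, and 0 were called by DESeq2, the likelihood ratio test or limma-voom. However, 2 were lower with library totals and 3 with upper quartile factors. The list did not pass with the main scaling (camera adjusted p = 0.645, and adjusted p = 0.749 with an estimated correlation). AGA2, STE6, BAR1 and STE2 were at -0.56 ± 0.26, 0.24 ± 0.17, -0.27 ± 0.21 and -0.30 ± 0.28, of which STE6 turned negative with library totals (-0.09) and upper quartile factors (-0.15) and STE2 positive without deletion library 1 (0.03). Of the MATalpha-specific genes, markers of the other mating type, MF(ALPHA)1 and STE3 fell from 4.37 ± 0.725 to 1.39 ± 0.133 CPM and from 9.69 ± 1.74 to 3.46 ± 1.24 CPM. In the list 2 of 4 fell, against 0 up and 3 down with p adjusted over the list alone (camera adjusted p = 0.232, and adjusted p = 0.46 with an estimated correlation). MF(ALPHA)2 and SAG1 did not pass, at -1.09 ± 0.40 and 0.10 ± 0.20, and SAG1 was at -0.22 with library totals and -0.29 with upper quartile factors. MF(ALPHA)2 was called lower with the edgeR likelihood ratio test (adjusted p = 0.0173), limma-voom (adjusted p = 0.046), library totals, upper quartile factors, the stricter filter, the replicate block and the GC offset, and without deletion library 1. Of 23 haploid-specific and pheromone response genes 7 fell and 1 rose, against 1 up and 6 down with p adjusted over the list alone (camera adjusted p = 0.225, and adjusted p = 0.715 with an estimated correlation). PRM1, PRM3 and FIG1 fell, with changes of -1.36 ± 0.19, -1.50 ± 0.28 and -2.13 ± 0.39, and RME1, the repressor of meiosis, rose by 2.72 ± 0.19. Of 20 sporulation genes 7 fell and the others did not pass, against 0 up and 4 down with p adjusted over the list alone (camera adjusted p = 0.127, and adjusted p = 0.388 with an estimated correlation). SPO21, DIT1, NDT80 and SPO13 fell, with changes of -1.32 ± 0.29, -0.99 ± 0.24, -0.69 ± 0.17 and -1.47 ± 0.40. Without wild-type library 1 the calls of MF(ALPHA)1 and STE3 ended (-1.45 and -1.26), without wild-type library 2 that of SPO13 (-1.27), and without either those of DIT1 (-1.05 and -0.90) and NDT80 (-0.60 and -0.76). With library totals and upper quartile factors 12 pheromone response genes each and 12 and 11 sporulation genes fell. Without wild-type libraries 1 and 2, 3 sporulation genes and 1 fell, and pheromone response genes that fell numbered 4 without wild-type library 1 and 14 without deletion library 2. Without deletion libraries 1 and 2, 4 and 5 histone genes rose and 3 and 2 fell. In these settings 4 pheromone response genes rose. In addition, 2 MATa-specific genes were lower without either of them, and without deletion library 2 STE6 passed upward (0.34, edgeR adjusted p = 0.0286).

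In all, 21 of 35 lists passed camera with the preset correlation, 13 up and 8 down. With the correlation estimated from the 2 residual degrees of freedom, camera called 0 of the 35, with 7 at an unadjusted p below 0.05 and a smallest camera adjusted p of 0.145. Lists with an estimated correlation below the preset 0.01 lost their calls too. The proteasome list (-0.0183) went from a camera adjusted p of 1.46e-06 to 0.232, and ribosome biogenesis (0.00495) from 1.63e-19 to 0.145. The loss of all calls therefore does not show that correlation between genes produced them. By contrast fry, which asks whether the genes of a list move on balance in either direction without comparing them with other genes, called 24. Leaving out a single library also changed the call of 5 lists. Besides the loss for translation factors, the iron regulon passed upward without deletion library 1 (camera adjusted p = 0.0339), and without deletion library 2 the chaperones passed upward (camera adjusted p = 0.0149) and the pheromone response and thiamine lists downward (camera adjusted p = 0.00934 and 0.0498). The amino acid biosynthesis and translation factor lists passed camera but not fry (fry adjusted p = 0.0883 and 0.0872).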

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

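The GC content offset and the thinning to equal depth were chosen after the results were seen. No gene called in both was called in opposite directions between the main test and any alternative. With DESeq2, the likelihood ratio test, limma-voom, RLE factors, other filters, gene sets, the authors' table, the GC offset, thinning and an adjusted p below 0.1, the genes higher in the deletion numbered 1580 to 1907 and the lower ones 1430 to 1889. Scaling mattered more for the lower genes, which numbered 2328 with library totals and 2508 with upper quartile factors against 1543, because these factors moved the median of all genes by -0.33 and -0.39. A log2 fold change of at least 1 left 1061 higher and 997 lower genes. Leaving out each library in turn gave 1045 (without wild-type library 1) to 2281 higher and 915 (without wild-type library 1) to 2179 lower genes, and without wild-type library 2 there were 1073 and 939. With 1 library left, a strain was assumed to vary like the other. The deletion pair spread more than the wild-type pair, so the estimated spread was larger when a wild-type library was left out. Replicate numbers did not pair the libraries (correlation of deviations across genes -0.07), and the replicate block, which leaves 1 residual degree of freedom, gave 1649 higher (1589 shared), 1667 lower (1490 shared) and 20 lists, the translation factors being lost. Of 35 lists, 20 to 24 passed under the alternatives and 0 with an estimated correlation, against 21, and leaving out each library gave 20 to 24. Reversals concerned genes without a call. STE6 was at -0.0865 with library totals and -0.150 with upper quartile factors, SAG1 at -0.222 and -0.293, and STE2 ranged from -0.702 (without deletion library 2) to 0.0320 (without deletion library 1), and the cause was not tested. Of the 173 named genes with a fold change, 8 lost their call without wild-type library 1 and 7 without wild-type library 2.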

Other observations

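The groups and tests in this part were all chosen after the results were seen. Of 16 genes for glycogen and trehalose metabolism, 15 rose in the deletion (edgeR quasi-likelihood test over all genes) with a median log2 fold change of 3.74, and 12 of the 16 are also in the general stress list. GPH1, glycogen phosphorylase, rose by 5.47 ± 0.30, PGM2, phosphoglucomutase, by 5.39 ± 0.33 and GLC3, the glycogen branching enzyme, by 4.87 ± 0.23, so genes of glycogen synthesis and breakdown rose together, and GLG2 did not pass, at 0.62 ± 0.28. Of 10 genes for eisosomes and plasma membrane domains, 8 rose, with LSP1 going from 459 ± 83.2 to 6101 ± 1368 CPM (SD, n = 2) and NCE102 from 419 ± 29.3 to 6381 ± 374 CPM, while FHN1, a paralog of NCE102, fell by 0.68 ± 0.21 and SEG1 did not pass, at -0.08 ± 0.16. In the protein kinase A pathway 10 of 14 genes rose and 1 fell, with TPK2 up by 3.60 ± 0.20 and TPK3 down, at -0.86 ± 0.17. With library totals, 8 eisosome, 15 storage carbohydrate and 9 protein kinase A pathway genes rose.

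Of 24 genes for the origin recognition complex, the replicative helicase and its partners and the DNA polymerases, 15 fell and 9 did not pass, with a median of -0.88 and no test of the group as a whole, and with library totals 20 fell. PSF1 fell by 2.03 ± 0.33, POL12 fell by 1.92 ± 0.26 and MCM5 fell by 1.47 ± 0.24, and MCM4 did not pass, at -0.14 ± 0.24. Of 72 snoRNA genes 36 fell, 34 did not pass and 2, snR11 and snR64, rose, with a median of -1.12. With library totals 48 of them fell and 1 rose, with a median of -1.45. Of 60 tRNA genes 24 fell, 34 did not pass and 2 rose, tA(UGC)O and tP(UGG)N1, while 30 fell with library totals. Of the 24 that fell in the main test, 10 had at most 3 counts in each deletion library, so their changes are uncertain in size. SCR1, the RNA of the signal recognition particle, went from 235 ± 3.26 to 43.1 ± 32.3 CPM. Genes for snoRNAs and snRNAs took 0.294% and 0.265% of counts in the wild type and 0.143% and 0.104% in the deletion.

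General stress genes were higher and ribosomal protein genes lower in the deletion, and 3 explanations other than the genotype acting directly were weighed. Log2 fold changes correlated with GC content across genes (Spearman 0.21, genes not being independent replicates), but after a GC offset that brought this to 0.02 the median of the ribosomal protein genes was -1.763 and that of the stress genes 3.44, which argues against a GC trend as the whole cause. Cells past the diauxic shift, where glucose is exhausted, cannot be told apart from the genotype, since FBP1, PCK1, ICL1, MLS1 and ADH2, chosen after their values were seen, had a median of -0.3385 (median SE 0.21), while 19 of 33 genes of the fixed list for such pathways rose, with a median of 0.90 and JEN1, a lactate transporter gene, at 3.89 ± 0.57. Less glucose left in the deletion cultures stays open as well, since the median of HXT2, HXT4, HXT6 and HXT7 was 6.239 while HXT1, a transporter gene induced by high glucose, was at 0.44 ± 0.27 and HXT3 rose by 2.14 ± 0.21, and no sugar measurement accompanies the libraries, whose cultures the labels place in a common range of optical density. The deletion of TOR1 itself, slower growth of the deletion strain, an adaptation of it or a difference between cultures may each account for the pattern. The design does not separate them, since the labels do not say that the libraries of a strain came from separate cultures.

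The 8 snoRNA genes annotated at 300 nt or more had a median of -1.893 (median SE 0.39, 6 lower), against -1.07 for the shorter ones. These values argue against a loss limited to RNA under 300 nt as the whole cause of the fall of 36 snoRNA genes. However, snR86, the longest (chromosome XIII, 762110 to 763113), and snR83 did not pass, at 0.67 ± 0.29 and -0.25 ± 0.26. A loss that reaches somewhat longer RNAs is therefore not excluded. Across all 72 the change did not rise with length (Spearman -0.24). If the deletion libraries carried less RNA without poly(A) tails, such RNAs outside the snoRNA class would fall as well, and the tested spliceosomal snRNAs with RPR1 and NME1 had a median of -1.443, with 4 of 6 lower, which is consistent with it. LSR1, the U2 snRNA, at -0.04 ± 0.28, and NME1, at -0.46 ± 0.37, did not pass, and all 6 had lower CPM in deletion library 2 than in library 1 (NME1 25.7 in library 1 and 11.2 in library 2, beside 25.7 and 24.7 in the wild type), so their levels differed between libraries of 1 strain as well. Lower snoRNA production, alongside the lower ribosome biogenesis genes, remains open as a hypothesis and was not tested, and total RNA libraries would be needed to separate it from carry-over.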
